A study of Homo sapiens with 6 samples.

How the data were processed

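Bulk RNA sequencing of sorted regulatory T cells (Tregs) was analysed from the table that the authors deposited. Per the labels' protocols, blood mononuclear cells of 3 healthy donors were frozen, thawed, stained and sorted as live CD45+CD3+CD4+CD25+CD127- cells into a CCR10+ and a CCR10- fraction. RNA was extracted from each cell pellet, and libraries were made with an Ovation low-input RNA sequencing kit, per the labels' protocols. Such kits amplify small amounts of RNA, so a transcript that is scarce in the pellet can be missed in one library and copied many times in another. Per the submitters' processing notes, reads were placed on hg38, STAR and DRAGEN were used, and DESeq2 1.30.1 made the comparison. The roles of STAR and DRAGEN, the annotation, the counting tool and its strand setting are not given in the sources used here. Reads of a gene and of a partner overlapping it on the opposite strand therefore could not be told apart, and ribosomal protein genes could share reads with their processed pseudogenes.

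The deposited table gives raw read counts per gene and library, whole numbers that were not normalized, for 12380 genes. Every gene in it had at least 11 counts over the 6 libraries, so low genes had been removed by the authors before deposit, by a rule that is not stated. The table also gives a mean normalized signal per gene, which the authors made by dividing the counts by size factors and averaging over the 6 libraries. The deposited log2 fold changes and their standard errors are those of CCR10+ over CCR10- Tregs, without shrinkage. A Wald score, the fold change over its standard error, was also deposited. The deposited p-values come from that Wald test, and the adjusted p-values from the Benjamini-Hochberg method with independent filtering, which left 481 genes without one. A DESeq2 refit of the deposited counts with donor and population as terms gave the deposited log2 fold changes to within 1.44e-09, so the authors' model held the donor. No column of values per sample was left unmapped.

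Gene IDs were matched to GENCODE 29 on GRCh38, the same build as hg38, which gave 12367 of the 12380 genes a position, and 12353 were annotated as protein coding. A pair of gene symbols, POLR2J3 and TBCE, each stood for 2 gene IDs and were kept apart by ID. Coordinates are 1-based. The genome sequence was not used here.

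Libraries were grouped by the sorted population, with 3 libraries in each, and each CCR10+ library was paired with the CCR10- library of its donor, whom the labels number 1 to 3. The pairing was also checked in the counts. The deviations from the population means correlated at 0.142, 0.188 and 0.127 within donors 1, 2 and 3, and each CCR10- library correlated below 0 with the CCR10+ libraries of the other donors. The values across donors are no separate evidence, since deviations from a mean sum to 0 and positive values within donors push the rest down. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom over genes lay between 40.5 and 132. Because the donors are separate people, the p-values of the tests of single genes measure the spread among these 3 donors.

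The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, two-sided) with donor and population as terms, TMM scaling and robust estimation. The filterByExpr function with its default settings kept 11592 genes and set 788 aside. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM, counts scaled by TMM to a library of 1000000, given as mean ± SD over 3 libraries, and log2 differences within a donor used a prior count of 2. Total counts ran from 7452416 to 9000851 per library, so 10 counts correspond to just over 1 CPM. Where a population had no counts for a gene, a fold was given only as a lower bound against a floor of 3 counts over its 3 libraries, which covers counting error only.

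The genes named in the text followed a rule fixed before the data were examined. It took the sorting-gate genes and FOXP3, the 10 largest changes in each direction past the threshold, and, since fewer than 5 genes passed, the 10 genes of smallest p in each direction with an average of at least 1 logCPM and the same direction in all 3 donors. From each gene list it took up to 4 members past the threshold or, where none passed, the 2 of highest mean expression. Genes without an approved-style symbol, immunoglobulin and T cell receptor segments, sex-linked marker genes and genes whose level depends on a common genotype were left out of the naming. The results of some genes that the rule covers are not reported here. Any other gene named is said to have been chosen after its values were seen.

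A total of 28 gene lists were also fixed before the data were examined, from textbook knowledge. They cover the sorting gate, Treg identity, naive and central memory T cells, effector and memory T cells, skin homing, gut homing, chemokine receptors, Th1, Th2, Th17 and Th22, follicular helper, tissue repair Tregs, proliferation, interferon response, glycolysis, vitamin D and retinoid response, AHR response, cytoplasmic ribosomal proteins, mitochondrial transcripts, immediate early and heat shock genes, and the marker genes of B cells, plasma cells, monocytes, dendritic cells, NK and CD8 T cells, platelets, red cells and neutrophils. Each was tested with camera (limma 3.58.1, voom values, two-sided) at a preset inter-gene correlation of 0.01, adjusted over the 27 lists that had a member among the genes tested. At this preset its p-values weigh a list's genes, taken as nearly independent, against the other genes and do not measure the spread among the donors. The lists were tested again with a correlation estimated from the residuals, of which only 2 degrees of freedom remained, and with fry. The edgeR p-values of members were also adjusted over each list alone. That adjustment was not corrected across the lists, so a pass there depends on the list and is weaker than one over all genes.

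The tests were tried on simulated counts drawn from these libraries' means, sizes and dispersions for CCR10+ against CCR10- Tregs, in 5 draws with 200 changed genes each and 11155.6 genes tested on average. The edgeR test called 8.64% of the genes changed 2-fold, 48.9% of those changed 4-fold and 69.2% of those changed 8-fold. Unchanged genes made up 3.86% of the edgeR calls and 23.8% of the DESeq2 calls. The counts were drawn with the dispersions that edgeR estimated, which may favour edgeR, so these shares do not compare the tools evenly. A naive T cell list lowered 1.5-fold was called by camera in 5 of 5 draws, and a draw with no change gave 0 lists, 0 edgeR genes and 3 DESeq2 genes. The simulated genes varied independently of each other, so these draws cannot show how often camera calls an unchanged list whose genes move together.

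Alternatives fixed before the data were examined were a fit without the donor, DESeq2 size factors, upper-quartile or plain library-size scaling, other filters and thresholds, DESeq2 1.42.0 and limma-voom in place of edgeR, fewer gene classes, a non-robust fit, and leaving out each donor or each library. An edgeR likelihood ratio test, DESeq2 on the genes kept by filterByExpr, a DESeq2 fit without the donor, upper-quartile scaling and single-library omission for the lists, and refits of the authors' comparison were added after the data had been seen.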

Results

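The transcriptomes of CCR10+ and CCR10- Tregs were compared by bulk RNA sequencing. Tregs are CD4 T cells that restrain immune responses, and CCR10 is the receptor for CCL27 and CCL28, chemokines of skin and mucosal epithelia. The series asks how Tregs that carry this receptor differ in transcription from those that do not. Both fractions were sorted from the blood of each of 3 healthy donors, which gave 3 libraries per population and 6 in all. The CCR10- libraries of donors 1, 2 and 3 held 8698116, 7831211 and 8705554 counts, and the CCR10+ libraries held 7452416, 8099359 and 9000851. Between 11701 and 12093 of the 12380 genes in the table had at least 1 count in a library.

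The transcript of the sorting receptor was scarce in both populations. CCR10 (ENSG00000184451.5) stood at 5.76 ± 1.97 CPM (SD, n = 3) in CCR10+ Tregs and at 3.58 ± 3.41 CPM (SD, n = 3) in CCR10- Tregs, on 11 to 67 counts per library. Its log2 fold change was 1.07 ± 1.25 (SE), and it was higher in the CCR10+ library of 2 of 3 donors. A difference was not detectable at this depth by edgeR's quasi-likelihood test (unadjusted p = 0.413, adjusted p = 0.977). Without replicate 1, 2 or 3, the log2 fold change was 0.49, 0.73 or 1.88. CCR10 lies on chromosome 17 at 42678889 to 42683917 of GRCh38 and overlaps CNTNAP1 on the opposite strand, so reads of the pair could not be told apart.

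FOXP3, the transcription factor that defines Tregs, was higher in the CCR10+ library of all 3 donors. It averaged 684 ± 247 CPM (SD, n = 3) in CCR10+ and 425 ± 97.2 CPM (SD, n = 3) in CCR10- Tregs, a log2 fold change of 0.64 ± 0.20 (SE). IL7R, which encodes the CD127 used to gate Tregs as negative cells, was lower in all 3 donors, at 517 ± 245 against 771 ± 242 CPM (SD, n = 3) and a log2 fold change of -0.66 ± 0.19 (SE). IL2RA, which encodes CD25, was higher in all 3 donors by 0.38 ± 0.18 (SE) on the log2 scale. Neither FOXP3 nor IL7R passed over all genes by edgeR (unadjusted p = 0.00956 and 0.00749, adjusted p = 0.941 for both). Adjusted over the list alone, IL7R was the 1 gene of the 6 sorting-gate genes that passed, against 0 over all genes tested (edgeR, adjusted p = 0.0449). Adjusted over the naive and central memory list, which also holds IL7R, the same p-value did not pass (edgeR, adjusted p = 0.0774). CD4, CD3E and PTPRC, which encodes CD45, had log2 fold changes of 0.12, 0.10 and -0.10. The gate list as a whole did not pass (camera, adjusted p = 0.991). FOXP3, on chromosome X at 49250436 to 49264826, overlaps CCDC22 on the opposite strand.

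**Figure D1:**
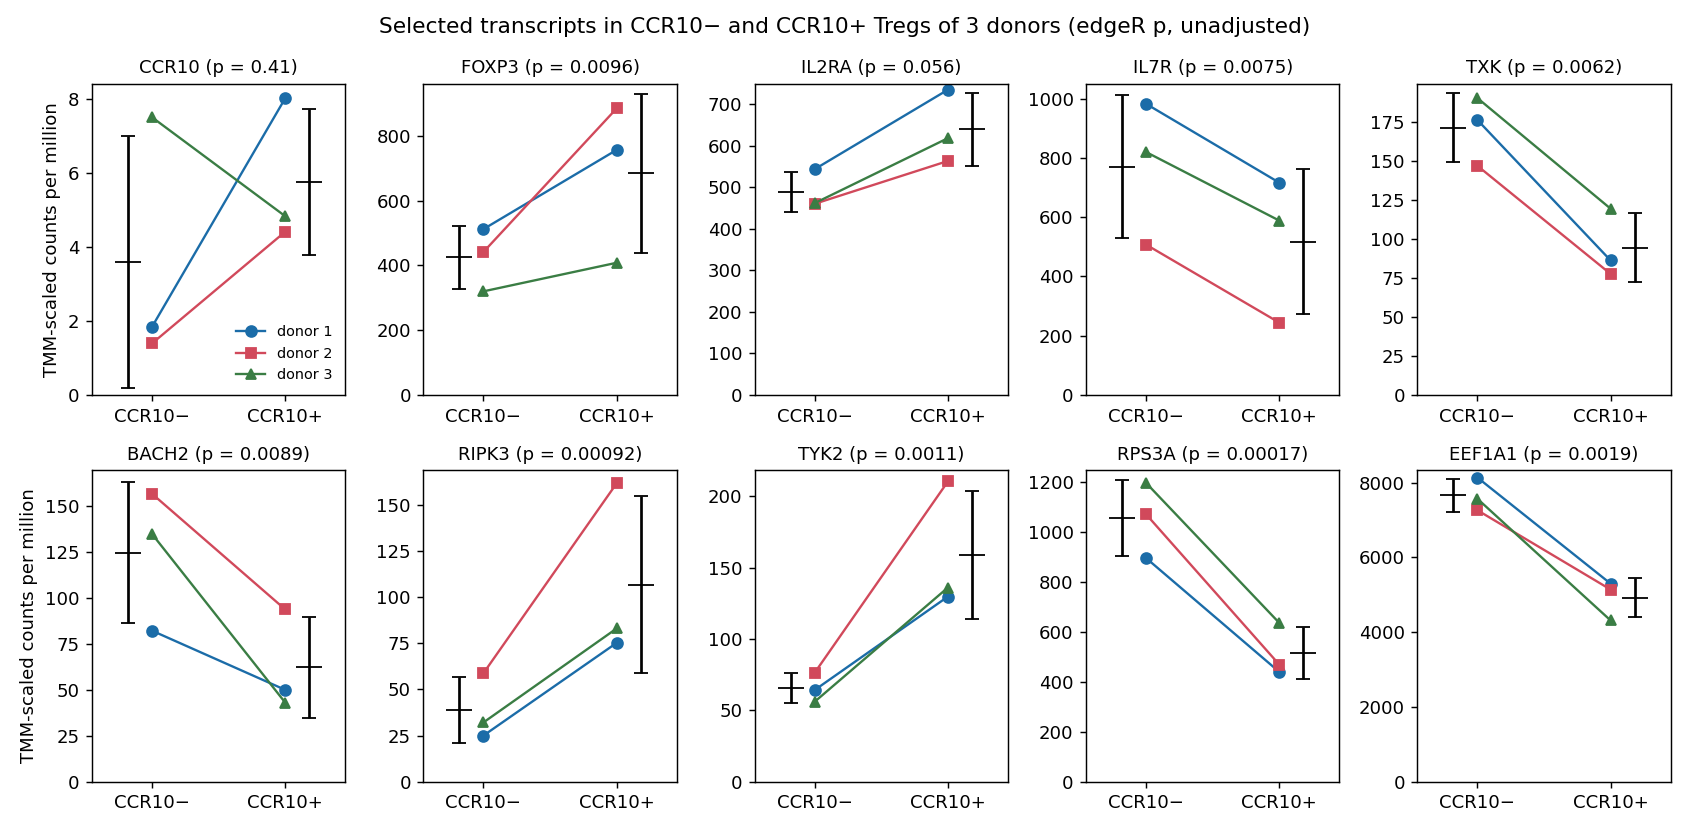
CPM of 10 transcripts in the CCR10- and CCR10+ library of each donor, joined by a line per donor, with the mean and SD (n = 3) of each population beside the points and the unadjusted edgeR p in each title. CCR10 went up in 2 donors and down in 1, FOXP3 was higher in all 3 CCR10+ libraries, and IL7R, TXK, BACH2, RPS3A and EEF1A1 were lower in all 3; none passed after adjustment (adjusted p = 0.941, and 0.977 for CCR10).

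No single gene passed across the transcriptome in the main test. By edgeR's quasi-likelihood test, 0 of 11592 genes had an adjusted p under 0.05, the smallest adjusted p being 0.941, and 580 genes had an unadjusted p under 0.05, with 379 higher and 201 lower in CCR10+ Tregs, where chance alone gives 579.6. Limma-voom also called 0 genes, with 718 at an unadjusted p under 0.05. DESeq2 called 35 over the whole table and 22 over the genes that edgeR tested. The biological coefficient of variation was 56.0%, and 27.4% of genes had the same direction in all 3 donors, where chance gives 25%. Without replicate 2, edgeR called 9 genes, 5 higher and 4 lower.

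The 10 higher genes of smallest p did not pass by edgeR (adjusted p = 0.941 for each). RIPK3, a kinase of necroptosis, stood at 107 ± 47.9 against 38.7 ± 17.9 CPM (SD, n = 3), a log2 fold change of 1.47 ± 0.31 (SE). TYK2, a kinase that signals for interferon and interleukin receptors, stood at 159 ± 44.9 against 65.6 ± 10.3 CPM (SD, n = 3), a log2 fold change of 1.25 ± 0.27 (SE). C3orf18 had a log2 fold change of 4.38 ± 0.80 (SE) from 5 to 27 counts in CCR10- and 139 to 277 in CCR10+ libraries, and overlaps HEMK1 on the opposite strand. MZB1, a chaperone of antibody-secreting B cells that other cells can express, had 0 counts in the CCR10- libraries and 16, 14 and 710 in the CCR10+ libraries. Its mean CPM was at least 223-fold higher against a floor of 3 counts over the CCR10- libraries. Most of the reads lay in replicate 3, so this is no bound for each donor. The log2 differences within donors 1, 2 and 3 were 3.33, 3.13 and 8.28. The inositol kinase IP6K1, the F-box gene FBXL16 and the RING finger gene RNFT2 had log2 fold changes of 1.98, 1.62 and 2.74. SIPA1L3, LMF2 and the calpain subunit CAPNS1 had log2 fold changes of 1.38, 1.37 and 0.89. RIPK3 lies on chromosome 14 at 24336021 to 24340045, TYK2 on chromosome 19 at 10350529 to 10380676, C3orf18 on chromosome 3 at 50558025 to 50571027, and MZB1 on chromosome 5 at 139387480 to 139390081.

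Likewise, the 10 lower genes of smallest p did not pass by edgeR (adjusted p = 0.941 for each). RPS3A, a small-subunit ribosomal protein on chromosome 4 at 151099573 to 151104652, stood at 515 ± 106 CPM (SD, n = 3) in CCR10+ and 1054 ± 151 CPM (SD, n = 3) in CCR10- Tregs, a log2 fold change of -1.04 ± 0.17 (SE). EEF1A1, the elongation factor that brings tRNA to the ribosome, stood at 4921 ± 529 against 7661 ± 443 CPM (SD, n = 3), a log2 fold change of -0.64 ± 0.15 (SE). RPL7, RPL9 and TPT1, the translationally controlled tumour protein, had log2 fold changes of -0.81, -0.79 and -0.71. VMA21, an assembly factor of the vacuolar proton pump, and TEX2 had log2 fold changes of -1.71 and -1.76. CDC42SE2 had a log2 fold change of -0.81, and MPZL1 one of -3.30 that rested in part on 584 counts in 1 CCR10- library. RPS3A, RPL7 and RPL9 overlap SH3D19, RDH10 and LIAS on the opposite strand, and they have processed pseudogenes, so their counts are uncertain.

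Genes of naive and central memory T cells were lower in CCR10+ Tregs as a set. Of 26 members, 24 had a lower estimate and 9 were lower in all 3 donors, with a median log2 fold change of -0.43 (camera, adjusted p = 2.33e-06; adjusted p = 0.757 with an estimated correlation, which did not pass). In the 3 other splits of the 6 libraries that part every donor's pair, camera gave this list adjusted p = 0.746, 0.0331 and 0.566. The donors' medians were -0.36, -0.17 and -0.49, and without replicate 3, its CCR10- library or its CCR10+ library the median was -0.26 in each case (camera, adjusted p = 0.00276, 0.00294 and 0.00300). These omissions are in effect the same test, since a library without its partner adds nothing to the contrast with the donor in the model. No member passed alone, over all genes or adjusted over the list alone, and 6 had an unadjusted edgeR p under 0.05. These 6, named after their values were seen, were the kinase gene TXK (log2 fold change -0.87 ± 0.25, SE), IL7R, the repressor gene BACH2 (-1.03 ± 0.31), IGF1R (-0.65), TCF7, a transcription factor of naive and memory T cells (-0.50), and ACTN1 (-0.72). The members of highest expression, LEF1 and FOXP1, had log2 fold changes of -0.27 and -0.15, and the lymph node receptor CCR7 one of -0.44. CD27, chosen after its values were seen, had a higher estimate of 0.52.

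Effector and memory genes and Treg identity genes were higher in CCR10+ Tregs as sets, by smaller margins. Of 30 effector and memory genes, 22 had a higher estimate and 7 were higher in all 3 donors, with a median log2 fold change of 0.28 (camera, adjusted p = 0.0152; adjusted p = 0.806 with an estimated correlation). Of 27 Treg identity genes, 19 had a higher estimate and 7 were higher in all 3 donors, with a median of 0.29 (camera, adjusted p = 0.0457; adjusted p = 0.806 with an estimated correlation). The donors' medians were 0.33, 0.09 and 0.04 for the effector and memory list and 0.29, 0.24 and 0.08 for Treg identity. CTLA4, BATF, TNFRSF4, TNFRSF1B and TIGIT, named for their membership alone, are in both lists, so these are not separate results. No member of either list passed, over all genes or adjusted over the list alone. AHNAK and CD44, the most expressed effector and memory genes, had log2 fold changes of 0.30 and 0.05, and IL10RA and IKZF2, which encodes Helios, of 0.29 and 0.14. Members at an unadjusted edgeR p under 0.05, named after their values were seen, were LMNA (2.06 ± 0.66, SE), CD74 (0.65 ± 0.24) and the galectin gene LGALS1 (0.74 ± 0.29) in the first list. In the second they were FOXP3, LRRC32, which encodes the TGF-beta docking receptor GARP (1.83 ± 0.71), and FCRL3 with the opposite sign (-0.52 ± 0.21). The Treg identity list did not pass without replicate 1, 2 or 3 (median log2 fold changes 0.11, 0.15 and 0.32; camera, adjusted p = 0.122, 0.278 and 0.0625), and the effector list did not pass without replicate 1 (median 0.12, adjusted p = 0.377) or without the donor in the model (no replicate block, median 0.26, adjusted p = 0.0675). Without replicate 3 the effector median was 0.15 (camera, adjusted p = 0.00915), and leaving out 1 library of a replicate moved both lists as leaving out the replicate did.

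Cytoplasmic ribosomal protein genes were lower in CCR10+ Tregs as a set, though not in every donor. All 67 had a lower estimate, 25 were lower in all 3 donors, and the median log2 fold change was -0.35 (camera, adjusted p = 6.56e-21; adjusted p = 0.806 with an estimated correlation, which was 0.784). By camera the list also passed in the 3 other splits of the 6 libraries that part every donor's pair (adjusted p = 5.74e-07, 1.34e-30 and 1.48e-05). The camera p-value of this list therefore does not by itself show a difference between the populations. The donors' medians were -0.21, 0.13 and -0.91, and without replicate 3 the median was -0.05 (camera, adjusted p = 0.0551), without its CCR10- or CCR10+ library -0.04 (adjusted p = 0.0610 and 0.0560), and without replicate 2 or either of its libraries -0.53 (adjusted p = 1.53e-53 without the replicate). Adjusted over the list alone, RPS3A passed (edgeR, adjusted p = 0.0114), against 0 genes over all genes tested. The most expressed members, RPL13A and RPS27, had log2 fold changes of -0.23 and -0.31. These transcripts made up 5.52 ± 1.42% of counts (SD, n = 3) in CCR10+ and 6.92 ± 0.35% (SD, n = 3) in CCR10- libraries, with the lowest share, 3.90%, in the CCR10+ library of replicate 3. That library also had the lowest median correlation with the others, 0.814, against 0.833 to 0.851 for the rest.

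**Figure D2:**
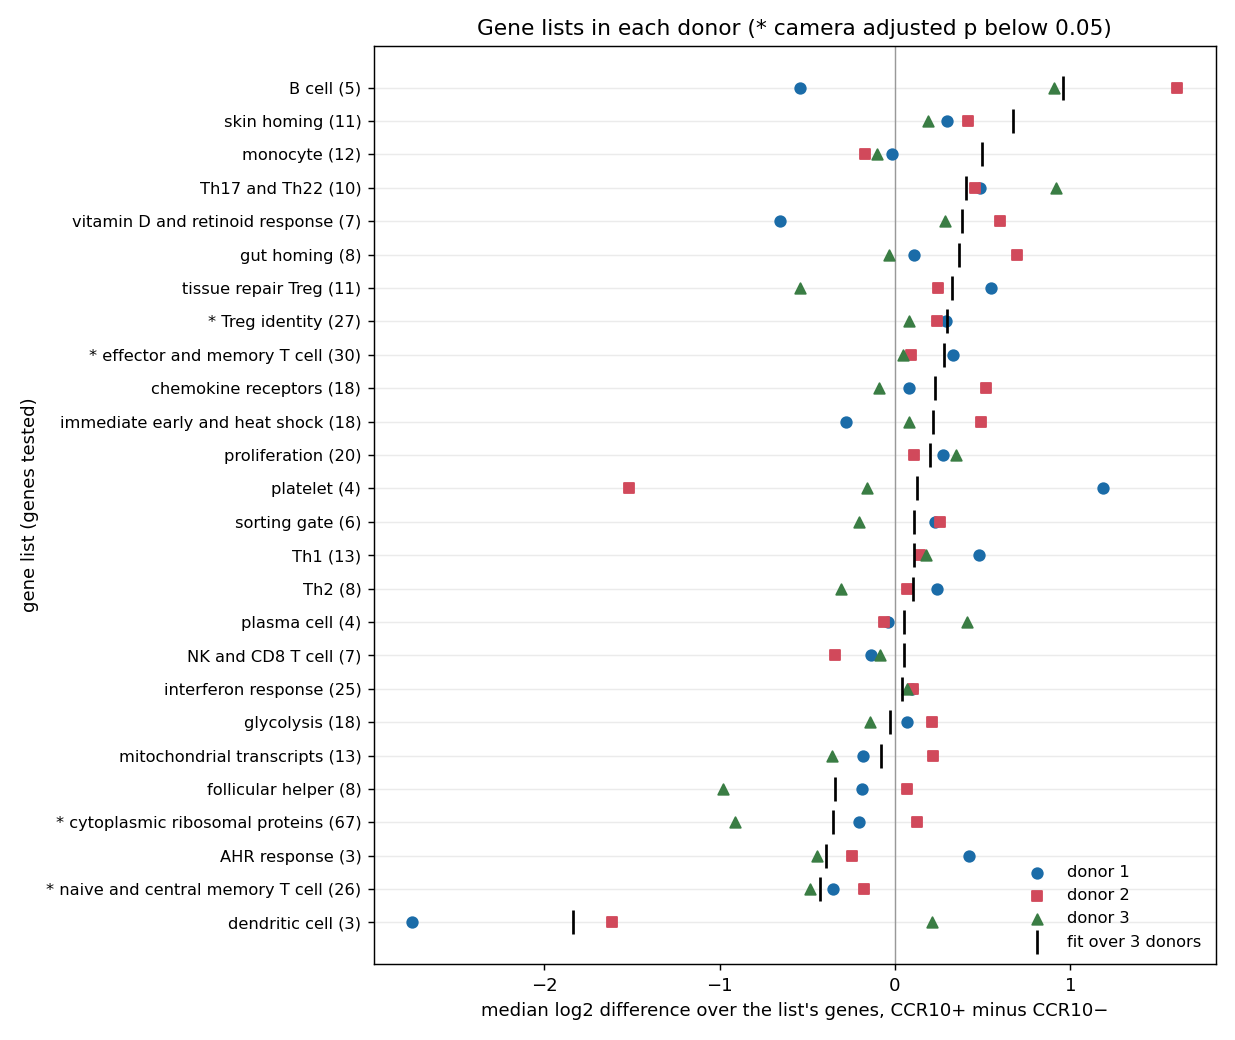
Median log2 difference, CCR10+ minus CCR10-, over the genes of each list with at least 3 genes tested, per donor (coloured points) and for the fit over 3 donors (black bars). The 3 donors of the naive and central memory list all lie below 0 (-0.36, -0.17 and -0.49), and those of the ribosomal protein list lie at -0.21, 0.13 and -0.91.

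Homing and chemokine receptor genes did not pass as sets. Of 11 skin homing genes, 10 had a higher estimate and 4 were higher in all 3 donors, with a median log2 fold change of 0.67 (camera, adjusted p = 0.265). Over the alternative runs this median lay between 0.34 and 0.73, and the list passed in none. SELPLG, which encodes the P-selectin ligand, and ITGAL had log2 fold changes of 0.39 ± 0.18 and 0.11 ± 0.20 (SE), and CCR4, the other chief skin-homing receptor, 0.06 ± 0.19 (SE). In the gut homing list, 6 of 8 genes had a higher estimate (camera, adjusted p = 0.655). The integrin gene ITGA4 of this list went the other way, at 150 ± 54.3 against 272 ± 97.7 CPM (SD, n = 3), lower in all 3 donors with a log2 fold change of -0.86 ± 0.23 (SE). ITGB7, the list's other integrin gene, chosen after its values were seen, had a higher estimate of 0.35 ± 0.34 (SE), higher in 2 of 3 donors. ITGA4 passed when adjusted over the list alone (edgeR, adjusted p = 0.0317), where 0 genes passed over all genes tested (adjusted p = 0.941). CXCR3 had a log2 fold change of 0.40 ± 0.25 (SE). Of 18 chemokine receptor genes, 12 had a higher and 6 a lower estimate (camera, adjusted p = 0.709).

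No helper lineage list passed by camera. Of 10 Th17 and Th22 genes tested, 8 had a higher estimate (adjusted p = 0.265), with RORA and ADAM12 at log2 fold changes of -0.03 and 0.45. Tissue repair Treg genes had a higher estimate in 9 of 11 (adjusted p = 0.265), with PRDM1 at 0.43 and GATA3 at 0.19. Th1 genes were split 8 to 5 (adjusted p = 0.655), with RUNX3 at 0.11. Th2 genes were split 5 to 3 (adjusted p = 0.897), with STAT6 at 0.15, and follicular helper genes 4 to 4 (adjusted p = 0.886), with TOX, a transcription factor of follicular helper and chronically stimulated T cells, at 0.62 ± 0.25 (SE) and SH2D1A at 0.19. No member of these lists passed, over all genes or adjusted over the list alone.

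Cell state lists did not pass either by camera. Proliferation genes were higher in 13 of 20 estimates (adjusted p = 0.655), with MKI67 and TUBB at log2 fold changes of 0.24 and 0.08. Interferon response genes were split 14 to 11 (adjusted p = 0.669), with OAS2 at -0.32. Of 18 glycolysis genes, 12 had a lower estimate (adjusted p = 0.886), with GAPDH at -0.05 and PKM at -0.33. The vitamin D and retinoid list was split 4 to 3 (adjusted p = 0.655), with RARA at 0.38 and the retinal reductase gene DHRS3 at -1.92 ± 1.02 (SE). DHRS3 ran from -3.31 to -0.53 over the alternative runs, and it passed without replicate 2 (-3.31, edgeR, adjusted p = 0.00132). In replicate 2 alone DHRS3 went the other way, from 81 to 143 counts, so this pass left out the donor that disagreed. The AHR list had 3 genes tested (adjusted p = 0.793), with AHR at -0.66 and its target TIPARP at 0.45. Immediate early and heat shock genes were higher in 13 of 18 estimates (adjusted p = 0.655), with the chaperone genes HSPA8 and HSP90AB1 at -0.23 and -0.55. Mitochondrial transcripts were lower in 12 of 13 estimates (adjusted p = 0.0838), with MT-CO1 at -0.05 and MT-ND4 at -0.08. They made up 6.90 ± 1.48% of counts (SD, n = 3) in CCR10+ and 7.30 ± 0.53% (SD, n = 3) in CCR10- libraries.

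The marker lists of other blood cells did not pass as sets. By camera the adjusted p was 0.655 for the B cell, plasma cell, monocyte, dendritic cell and neutrophil lists, 0.703 for NK and CD8 T cells and 0.886 for platelets, and no red cell gene was tested. Higher and lower estimates were split 3 to 2 for B cell, 2 to 2 for plasma cell, 6 to 6 for monocyte, 1 to 2 for dendritic cell, 4 to 3 for NK and CD8 T cell and 2 to 2 for platelet genes. MZB1 passed when adjusted over the plasma cell list alone (edgeR, adjusted p = 0.000795), while its fellow list members XBP1 and FKBP11 had log2 fold changes of -0.25 and 0.35. Some monocyte and NK transcripts were concentrated in both libraries of replicate 2. The cytotoxic granule gene GNLY had 691 and 516 counts in the CCR10- and CCR10+ library of that replicate and at most 27 in any other library, and the monocyte gene VCAN had 888 and 536, against 3 to 212 elsewhere. PRF1 and CTSS had log2 fold changes of 0.05 and -0.13, and the B cell genes CD79B and CD72 of 2.03 ± 1.19 and 0.96 ± 0.98 (SE). ITM2C and SERPINF1 of the dendritic cell list had log2 fold changes of 0.50 and -2.05, TUBB1 and CLU of the platelet list 0.51 and -1.44, and CSF3R, the neutrophil gene tested, -2.89 ± 1.75 (SE). The median or mean and the test differed in sign for the Th2, follicular helper, vitamin D and retinoid, monocyte, NK and CD8 T cell, and platelet lists.

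The authors' deposited table called 35 genes by DESeq2 at an adjusted p under 0.05, 24 higher and 11 lower in CCR10+ Tregs. Refits of the same model to the counts of the authors' deposited table without replicate 1, 2 or 3 called 24, 6 and 80 genes, with 12, 2 and 14 of the 35 among them. Of the 10 higher genes of smallest p named above, 9 were among them, all except MZB1, and of the 10 lower genes 6 were. In the authors' deposited table the smallest adjusted p belonged to C3orf18 (log2 fold change 4.40 ± 0.75, SE, adjusted p = 5.16e-05) and RPS3A (-1.04 ± 0.20, adjusted p = 0.000878). RIPK3 and TYK2 had adjusted p-values of 0.0135 and 0.0184 in the authors' deposited table, where CCR10, FOXP3 and IL7R did not pass (adjusted p = 0.892, 0.220 and 0.187). Genes beyond the naming rule, chosen after their values were seen, included PTPN13, a phosphatase of the Th17 and Th22 list (4.40 ± 1.15, adjusted p = 0.0473 in the authors' deposited table), whose counts were 1, 21 and 2 in CCR10- and 25, 20 and 585 in CCR10+ libraries. A count of 0 in at least 1 library was found for 12 of the 35 genes in the authors' deposited table. For 4 of them, SH3D21, OR5B21, LDHD and CLIC3, a whole population stood at 0. SH3D21 had 21 to 106 counts in CCR10+ libraries, LDHD 11 to 85, the olfactory receptor gene OR5B21 5 to 213, and CLIC3 had 6 to 199 counts in CCR10- libraries. The edgeR test covered 31 of the 35 genes and gave 30 of these an unadjusted p under 0.05, and 0 an adjusted p under 0.05 (adjusted p = 0.941 for each).

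**Figure D3:**
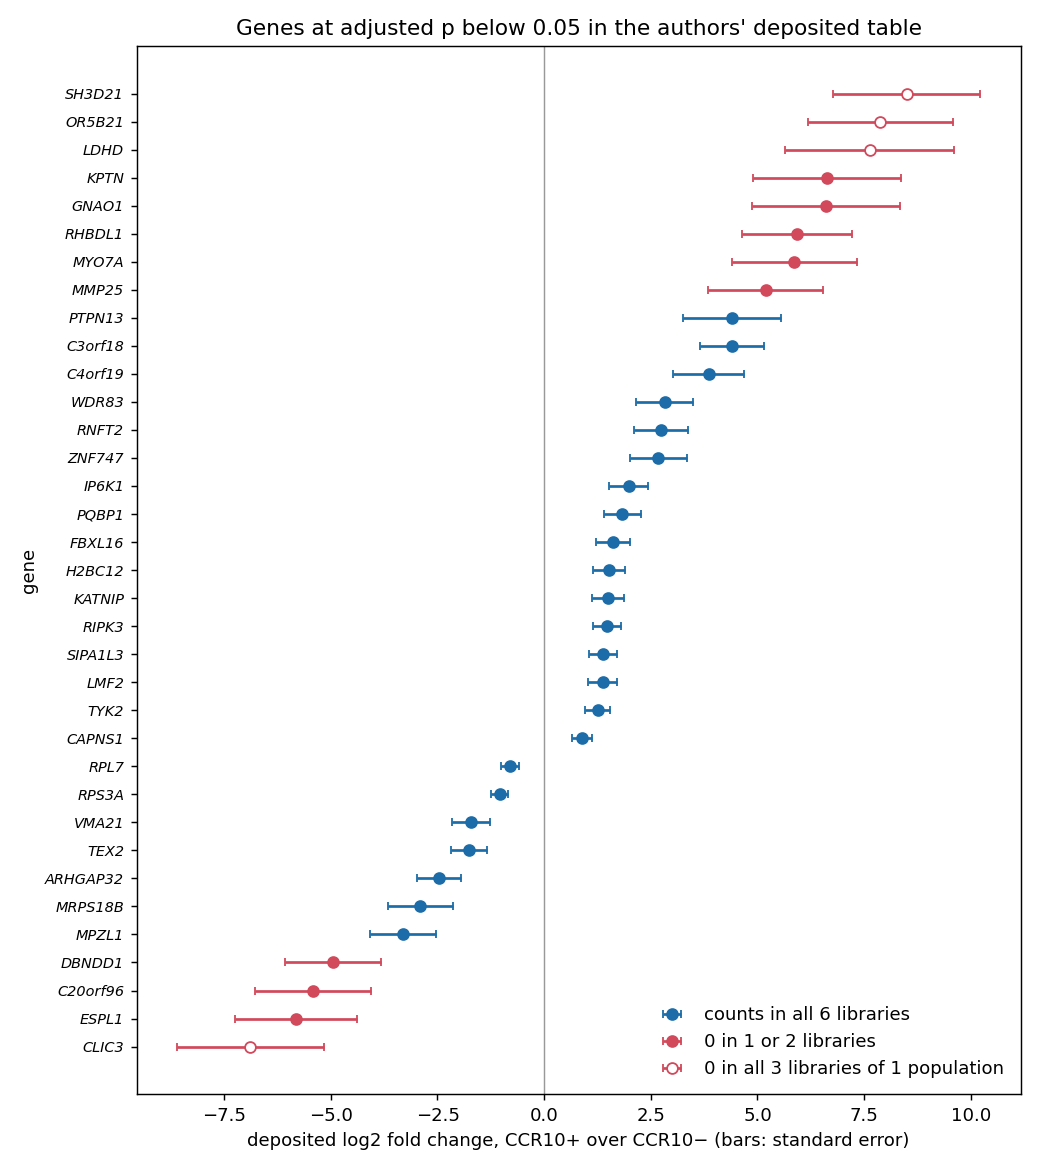
Log2 fold change, CCR10+ over CCR10-, with its standard error, of the 35 genes at an adjusted p under 0.05 in the authors' deposited table, as deposited. Red points mark the 12 genes with a count of 0 in at least 1 library, and the 4 open points have a whole population at 0, so their fitted folds are no measured sizes.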

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

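The edgeR likelihood ratio test, DESeq2 on the filtered genes, the DESeq2 fit without the donor, the single-library and upper-quartile runs of the lists and the refits of the authors' comparison were chosen after the data had been seen. The count of 0 changed genes by edgeR's quasi-likelihood test was also 0 under each other scaling, filter, threshold and gene class tried, without robust estimation, by limma-voom and with no replicate block. It was 35 by DESeq2 over the whole table, 22 by DESeq2 over the genes that edgeR tested, 12 by DESeq2 with no replicate block, 9 by edgeR's likelihood ratio test, and from 0 to 9 over the runs that left out a replicate or library, the 9 without replicate 2. Possible causes of the 35 DESeq2 calls are weighed under the other observations and were not settled. The cause of the other differences in these counts was not tested. No replicate block gave 493 genes at an unadjusted edgeR p under 0.05, ended the effector and memory list's call (median log2 fold change 0.26, adjusted p = 0.0675; 3 lists passed) and changed no other call. The CCR10 difference kept its sign and stayed short of the threshold in every alternative run, from 0.49 to 1.88 with replicates left out.

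By camera 4 lists passed, and 2 to 4 did with a replicate or library left out. With the donor in the model, leaving out 1 library of a pair is in effect leaving out the pair, so its result is no further support. With an estimated correlation or by fry 0 passed, and the medians, which those tests do not alter, were -0.43 for naive and central memory (adjusted p = 0.757 and 0.580), -0.35 for ribosomal proteins (0.806 and 0.729), 0.28 for effector and memory (0.806 and 0.580) and 0.29 for Treg identity (0.806 and 0.580); both work from 2 residual degrees of freedom. With upper-quartile scaling the Treg identity median was 0.23 (adjusted p = 0.0635). Over the omissions the median ran from -0.58 to -0.26 for naive and central memory, which passed in each (highest adjusted p = 0.00300), from -0.535 to -0.0407 for ribosomal proteins (highest 0.0610), from 0.12 to 0.26 for effector and memory (highest 0.410) and from 0.11 to 0.33 for Treg identity, which passed in none (lowest 0.0560). Mitochondrial transcripts passed, lower, in 5 alternatives: upper-quartile scaling, library size alone, and without replicate 2 or either of its libraries. No scaling moved the median of all genes by over 0.1 on the log2 scale.

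The authors' 35 calls numbered 6 to 80 in refits without 1 replicate, 12 with no replicate block and 35 without independent filtering. Of the 35 genes, 12, 2 and 14 were called again without replicate 1, 2 and 3. For named genes, 777 of 824 alternative values kept sign and side of the threshold, 28 had the opposite sign without passing either way, and 19 passed, 15 by DESeq2 and 4 without replicate 2. For the lists, 334 of 404 values kept both and 40 had the opposite sign without a call. No called value reversed. Alternatives planned for normalized values or for a table without counts were not run, since the table holds counts. At this depth CCR10 had 11 to 67 counts per library and a standard error of 1.25, and simulated 2-fold changes, at this depth and with 3 donors, were called in 8.64% of cases.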

Other observations

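The tests of plasma cell genes, of library depth, of exchanged labels and of called genes with a count of 0 were chosen after the results they bear on had been seen.

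Several genes of the fixed lists, chosen after their values were seen, went one way in all 3 donors, and neither they nor the genes named beside them passed by edgeR (adjusted p from 0.941 to 0.996). FOS, a subunit of the AP-1 transcription factor, stood at 58.7 CPM in CCR10+ and 20.8 in CCR10- Tregs, a log2 fold change of 1.47 ± 0.40 (SE, unadjusted p = 0.00481), and JUNB and JUN had log2 fold changes of 0.59 and 0.48, higher in all 3 donors, while FOSB (0.33) was higher in 2 and JUND (0.08) in 1. The chaperone genes HSP90AB1, HSP90AA1, HSPA8 and HSPH1, of the same fixed list, were lower in all 3 donors, by -0.55, -0.32, -0.23 and -0.49, while HSPA1A was higher in all 3 (0.51) and DNAJB1 in 2 (0.19). The replication licensing genes MCM5 and MCM4 were higher in all 3 donors (log2 fold changes 1.24 ± 0.39 and 0.80 ± 0.34, SE), while TOP2A and MCM2 were lower in all 3 (-0.91 and -2.00) and MCM3, MCM6 and MCM7 had lower estimates (-0.51, -0.18 and -0.02).

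The genes TNFRSF18 (GITR), TNFRSF9 (4-1BB) and TNFRSF8 (CD30) had higher estimates in all 3 donors, at log2 fold changes of 1.97 ± 0.89, 1.03 ± 0.59 and 3.36 ± 1.83 (SE), as did DUSP4 at 0.70 ± 0.34, whereas TNFRSF4 (OX40) was higher in 2 of 3 donors and ICOS in 1. TNFRSF8 was scarce, with 2, 15 and 0 counts in CCR10- and 54, 31 and 6 in CCR10+ libraries. The log2 differences of TNFRSF18 were uneven, at 0.67, 4.16 and 1.23 in donors 1, 2 and 3. TIGIT, GPR15, a colon-homing receptor, and STAT4, which transmits interleukin-12 signals, had lower estimates in all 3 donors, at -0.20, -1.23 and -0.70. These genes were picked from the fixed lists after their values were seen, and none passed by edgeR (adjusted p from 0.941 to 0.986).

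DESeq2 called 35 genes over the whole table and 22 over the genes that edgeR tested, where edgeR's quasi-likelihood test called 0 (580 at an unadjusted p under 0.05), with or without its filter; the choice of dispersion model stays open, as 96.8% of the called genes that edgeR tested, 30 of 31, had an unadjusted edgeR p under 0.05, which decides nothing for genes picked by a low p on the same counts. Transcripts missed altogether in a low-input library are argued against as the cause of all 35 calls, as 12 of the genes had a count of 0 in any library; for those 12 they stay open, with 34 genes of the table at 0 in all 3 libraries of one population and above 0 in all 3 of the other, against at most 21 in the 3 other splits that part every donor's pair. The 10 splits of the 6 libraries into 3 and 3, which make 7 distinct tests with the donor in the model, are too few for a share under 0.05. Of these splits, 6 part only 1 pair, and their contrast is that donor's own difference between CCR10+ and CCR10- libraries. Such splits compare the real populations in 1 donor and are no wrong grouping to set against the real split. DESeq2 called 35 genes in the real split and at most 45 in the 3 other splits that part every pair. In all, 4 splits, 3 distinct tests, gave at least 35 calls, the highest being 278 where 1 pair is parted. Camera called 4 lists in the real split and at most 3 in the 3 other splits that part every pair. In all, 3 splits, 2 distinct tests, called 4 lists, namely the real split and splits that part 1 pair. The 0 calls of edgeR, against at most 1, are met by all 10 splits whatever the data. A swap of the 2 labels within 1 donor stays open, as 0 of 3 donors had log2 differences that ran against the other donors' (Spearman's correlation under -0.05 across genes, which are not independent) but not all 3 ran clearly with them; CCR10 was higher in the CCR10+ library of 2 of 3 donors, and FOXP3, IL2RA and IL7R ran one way in all 3.

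Ribosomal protein transcripts were lower in CCR10+ libraries, with RPS3A, RPL7 and RPL9 among the named genes. A bias by transcript length is argued against: genes matched on length and mean expression had a median log2 fold change of 0.0604, against -0.35 for the list. The pattern may rest on 1 donor's libraries, since the 3 donors' medians were -0.21, 0.13 and -0.91. A factor that moves these transcripts together in any library was not decided: the largest list median of the other splits that part every pair, 0.41 in size, follows from the donors' medians. Camera called the list in each of those splits, as given above, so its call in the real split does not decide the matter. A difference between the populations themselves stays open. The list passed by camera (adjusted p = 6.56e-21) but not by camera with an estimated correlation (adjusted p = 0.806) or by fry (adjusted p = 0.729).

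Replicate 3 stood apart, with its CCR10+ library farthest from the rest, and it held 710 of the MZB1 counts. A lower depth of that library is argued against, as its total count ranked 6 of 6, the highest. The same library nonetheless had the fewest genes with at least 1 count, 11701, against 11858 to 12093 in the others. Why it held fewer genes was not tested. Plasma cells, which express CCR10 and MZB1 but which the CD3 and CD4 gate should remove, may have contributed. Over 16 other plasma cell genes tested the median log2 difference in replicate 3 was -0.0741, with 7 of them higher. SDF2L1 and ITM2C went from 3 and 20 counts to 137 and 135, and XBP1 and HSP90B1 from 646 and 2494 to 615 and 1406. POU2AF1 and ELL2 fell as well, from 45 and 74 counts to 20 and 25. CCR10 itself went from 67 to 46 counts in replicate 3, and TNFRSF13B from 6 to 0. Tregs express several of these genes. The deposited table, from which low genes had been removed, lacks the joining chain and immunoglobulin genes, and whether low counts are the reason is not given. A few plasma cells and expression by Tregs therefore stay open.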
